A study of Arabidopsis thaliana with 15 samples.

How the data were processed

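Leaf RNA of Arabidopsis thaliana (accession Landsberg erecta) was measured on Affymetrix ATH1 arrays of 1 colour, 15 in all. The plants were wildtype or carried a mutation in UVR8, which encodes a UV-B photoreceptor, or in HY5, which encodes a bZIP transcription factor of light signalling. Per the labels, plants grew for 3 weeks in compost at 21 °C under continuous white light of 25 µmol m-2 s-1, and the UV-B groups then received 3 µmol m-2 s-1 of UV-B for 4 h. Each of the 5 groups (wildtype in white light, wildtype under UV-B, uvr8-1 in white light, uvr8-1 under UV-B, hy5-1 under UV-B) has 3 arrays, labelled as biological replicates. No hy5-1 array was made in white light, so a UV-B response of hy5-1 cannot be computed. With 3 arrays per group, their number limits the precision.

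The deposited values are in log2 units and were made by the authors with RMA, which the submitters' processing notes name. RMA normalises probe intensities to a common distribution and summarises the probes of a probe set into 1 value. The RMA version, the background step and whether all arrays were processed in 1 run are not given in the sources used here. The values ran from 1.99 to 13.1, and the array medians lay between 4.31 and 4.40. No further normalisation was applied. The table held 22810 probe sets. The 64 control probe sets were set aside, and the remaining 22746 were tested without a filter on signal. The annotation used here paired 13513 of them with 1 gene, 503 with several genes and 8730 with none, and 13356 genes had a probe set of their own. Symbols and neighbouring genes came from a RefSeq gene table of assembly TAIR10.1, which matched 13436 of the 13513 single-gene probe sets. No genome build is named for the arrays, so no coordinates are given. CHS, HY5, UVR8 and COP1 had no probe set that this annotation pairs with them alone, and no values are given for these genes.

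Differences between groups were tested with limma 3.58.1 in R 4.3.3. A single linear model with a mean per group was fitted to all 15 arrays (10 residual degrees of freedom), followed by empirical Bayes moderation with default settings (3.09 prior degrees of freedom). The 7 contrasts were UV-B minus white light in wildtype and in uvr8-1, the difference of these responses (interaction), uvr8-1 minus wildtype under UV-B and in white light, and hy5-1 minus wildtype and minus uvr8-1 under UV-B. Tests were 2-sided, p-values were adjusted by the Benjamini-Hochberg method over the 22746 probe sets, and a probe set was called at an adjusted p under 0.05 with no fold minimum. A probe set was termed induced when it was called and at least 2-fold higher under UV-B in wildtype. Errors after ± are standard errors of a log2 difference from this model unless SD is written. The overlap of the mutants and the classes of induced probe sets share the wildtype UV-B arrays, so both were also computed on 20 simulated data sets in which the mutants did not differ from wildtype. These had independent residuals, and 20 more, added after the overlap was seen, had residuals correlated as observed between equally numbered wildtype and uvr8-1 arrays. Plots were drawn with matplotlib 3.10.9 and tables prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

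The contrasts, the tests, the rule for named genes, the alternatives and 20 gene lists were fixed before the data were examined. A gene was represented by its single-gene probe set with the highest mean over all arrays. Named genes are the 10 largest rises and 10 largest falls per contrast among called genes whose groups do not overlap (for the interaction, the 5 highest and 10 lowest), HYH, and up to 4 members per list with the smallest p. HYH belongs to the light-signalling list, which draws partly on published work on this series. Of the 365 genes in the 20 lists, 47 had a single-gene probe set. The 7 lists with 3 or more measured members were the flavonoid pathway, oxidative stress, photosynthesis, auxin, gibberellin and cell expansion, glucosinolate and tryptophan pathway, reference genes and root markers. The 13 lists with fewer were light signalling, phenylpropanoid and sinapate pathway, DNA repair, heat shock proteins, salicylate and pathogen response, jasmonate and wounding, circadian clock, leaf senescence, epidermis, trichome and guard cell markers, cell cycle, floral markers, seed storage markers and vascular markers. Because of this coverage, 16 gene families defined by symbol were added after the annotation was seen and before any test. They were UDP-glycosyltransferases, glutathione transferases, expansins, xyloglucan endotransglucosylases, cytochromes P450, thioredoxins and glutaredoxins, SWEET sugar transporters, WRKY factors, LEA proteins, histones, U-box proteins, calmodulin-like proteins, cellulose synthases and related genes, tubulins, bHLH factors and chloroplast-encoded genes. Lists and families were compared with the other genes by camera with a preset inter-gene correlation of 0.01 and again with the correlation estimated from the data, and fry tested whether a list moves on balance 1 way. All 3 used 1 probe set per gene and Benjamini-Hochberg adjustment over the lists of a contrast.

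Whether equal replicate numbers mark paired samples was checked by correlating the residuals of arrays about their group means. Between wildtype and uvr8-1, arrays of equal number correlated at 0.48 to 0.66 in white light and 0.45 to 0.68 under UV-B. Between lights, they correlated at 0.10 to 0.33 in wildtype and 0.21 to 0.33 in uvr8-1. The hy5-1 arrays did not pair with wildtype (0.0026 to 0.12) or uvr8-1 (−0.03 to 0.12). RNA and labelling quality was described by the 3' minus the 5' log2 value of the actin, GAPDH and ubiquitin control probe sets, and their mean is called the 3' to 5' index.

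The alternatives set beforehand were the replicate number as a block, a fit of only the compared groups, an intensity trend with a robust prior, array weights, median centring followed by quantile normalisation, removal of the dimmest 40% of probe sets, a 2-fold minimum, removal of probe sets that may bind several transcripts, the rank product with 100 permutations, and omission of each array in turn. The alternatives chosen after seeing the data were a block over the 12 wildtype and uvr8-1 arrays, omission of the replicate 1 arrays of every group, the 3' to 5' index as a covariate, its slope within the 12 wildtype and uvr8-1 arrays, and the hy5-1 array of lowest index alone. The procedure was tested on simulated data of 22746 probe sets with 200 changed ones. For UV-B minus white light in wildtype, limma recovered 22.4% of changes of 0.5, 83.6% of changes of 1 and 100% of changes of 2 on the log2 scale, and 5 of its 142 calls were unchanged probe sets. For the interaction, the recovered shares were 0%, 56.7% and 97% for the same sizes. For hy5-1 minus wildtype they were 25.4%, 83.6% and 100%, and 10 of 149 calls were unchanged probe sets. Camera found a list of 8 genes raised by 0.5 among 100 simulated lists, and 2 of the unchanged lists had an unadjusted p under 0.05. The simulated residuals were independent between probe sets and between arrays, so this test does not show how camera behaves on lists of correlated genes. The null distribution of the rank product was revised after it failed this test, when its first counts on the arrays had been seen, and in the revised form 58 of its 181 calls, 32%, were still unchanged probe sets.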

Results

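Transcript levels in leaves were measured on 15 arrays, 3 for each of 5 groups: wildtype in white light, wildtype under UV-B, uvr8-1 in white light, uvr8-1 under UV-B and hy5-1 under UV-B. UVR8 is a photoreceptor of UV-B and HY5 is a bZIP transcription factor that promotes light responses. By its title, the series asks which genes UV-B induces in wildtype and how these genes behave in the mutants. Every array gave a log2 value for each of 22746 probe sets, and the array medians lay between 4.31 and 4.40. The 3' minus 5' difference of the GAPDH control probe sets, a measure of how evenly transcripts are represented, was 2.65 ± 0.73 (SD, n = 3) in hy5-1. It was 0.97 ± 0.05 in wildtype under UV-B, 0.91 ± 0.11 in uvr8-1 under UV-B, 0.80 ± 0.15 in wildtype in white light and 1.25 ± 0.24 in uvr8-1 in white light. The difference between hy5-1 and wildtype under UV-B, 1.68, had an exact permutation p of 0.1, the smallest that 3 arrays against 3 allow. GAPDH was the control with the largest difference. That of ubiquitin was 0.65 (exact permutation p = 0.1) and that of actin 0.38 (exact permutation p = 0.3). Actin thus did not set the hy5-1 arrays apart, and the higher index of hy5-1 rests mainly on GAPDH and ubiquitin.

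**Figure D1:**
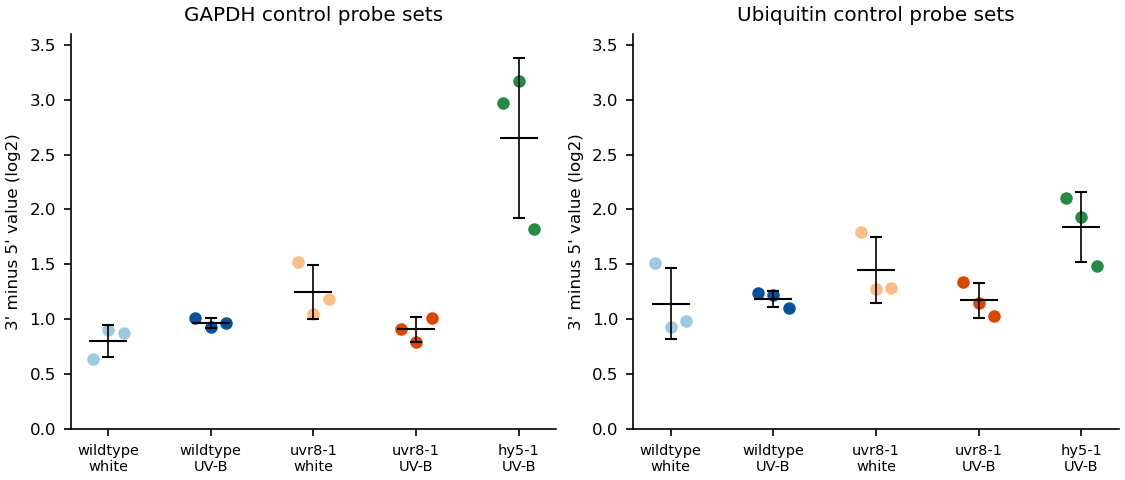
The 3' minus 5' value in log2 units (vertical axis) of the GAPDH and ubiquitin control probe sets for each of the 15 arrays, by group (horizontal axis); points are arrays and bars give mean and SD of 3 arrays. The hy5-1 arrays lie at 1.82 to 3.17 for GAPDH, above the 1.52 of the highest other array. For ubiquitin, hy5-1 replicate 3 (1.48) lies below uvr8-1 white light replicate 1 (1.80). Actin is not drawn.

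The comparison of wildtype plants under UV-B and in white light asked which genes UV-B induces. The largest rise of a named gene was that of AT2G41730, from a mean of 3.44 ± 0.17 to 11.76 ± 0.29 (SD, n = 3), a difference of 8.32 ± 0.17. It was followed by AT1G26380, which encodes an FAD-linked oxidase (6.81 ± 0.49), AT1G19020 (6.76 ± 0.42) and the small heat shock protein gene AT5G51440 (6.55 ± 0.26). AT4G39670 rose by 6.24 ± 0.52, the efflux transporter gene AT2G04050 by 6.05 ± 0.27 and the lectin gene AT3G16530 by 5.88 ± 0.44. UGT73B5, a glycosyltransferase gene, rose by 5.85 ± 0.39, the subtilase gene SBT3.5 by 5.82 ± 0.14 and the calcium-binding protein gene AT3G01830 by 5.70 ± 0.61. HYH, the closest homologue of HY5, rose by 4.48 ± 0.45 (adjusted p = 6.8e-06). The largest falls were those of the expansin gene EXPA8, which acts in cell wall loosening (−4.03 ± 0.24), and of AOP3, an enzyme of glucosinolate side chains (−3.90 ± 0.32). The lipase gene AT1G29660 (−3.53 ± 0.16), AT5G16030 (−3.37 ± 0.29), AT4G38690 (−3.35 ± 0.22) and AT1G54820 (−3.30 ± 0.26) also fell. The lipid transfer protein gene AT5G48490 (−3.24 ± 0.31), the transcription factor gene BZIP61 (−3.18 ± 0.35), AT1G78020 (−3.15 ± 0.38) and AT3G06070 (−3.12 ± 0.29) completed the 10. Adjusted p for these 20 genes lay between 3.04e-12 and 3.83e-05. For every gene named as one of the largest changes between 2 groups, the 3 arrays of a group did not overlap those of the other. The naming rule required this, so it is no further evidence, and chance alone gives it in 10% of genes. Of the 10 genes with the largest rises, 8 had a white light mean under 3.74, the limit of the dimmest 40% of probe sets, so the size and order of these rises depend on values near background. In all, 2776 probe sets were higher and 4165 lower under UV-B, 1602 and 1227 of them by at least 2-fold. The UV-B arrays of replicate 1 responded less than the others. Over the probe sets that changed at least 2-fold in the other genotype, the slope of a replicate's response on that genotype's mean response was 0.79, 0.95 and 1.04 for replicates 1, 2 and 3 of wildtype. It was 0.74, 1.02 and 0.98 for those of uvr8-1.

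Of the 7 measured genes of the flavonoid pathway, which makes UV-absorbing pigments, 5 rose in wildtype, over all genes and adjusted over the list alone. They were the flavonol glucosyltransferase gene UGT78D2 (2.96 ± 0.23), the flavonol rhamnosyltransferase gene AT1G06000 (2.79 ± 0.40), CHIL, which aids chalcone synthesis (2.65 ± 0.33), DFR of anthocyanin synthesis (2.27 ± 0.42) and the anthocyanin glucosyltransferase gene AT4G14090 (1.53 ± 0.33). The list's camera call (adjusted p = 0.0007) was lost with adjusted p = 0.288 with an estimated correlation. All 3 measured oxidative stress genes rose, over all genes and adjusted over the list alone: STZ, a zinc finger repressor (4.95 ± 0.75), AT2G21640 (4.92 ± 0.21) and the glutathione transferase gene GSTU25 (3.55 ± 0.33). Camera placed this list up (adjusted p = 4.28e-05, and 0.0206 with an estimated correlation). All 6 histone genes fell, among them HIS1-3 (−1.99 ± 0.22) and HTB11 (−1.41 ± 0.11), with a camera adjusted p of 8.4e-06 (0.0217 with an estimated correlation). Of 52 UDP-glycosyltransferase genes 18 rose and 4 fell, with a camera adjusted p of 2.08e-07 (0.00177 with an estimated correlation). UGT73C1 rose by 4.73 ± 0.20, UGT87A2 by 4.57 ± 0.14 and the hydroxycinnamate glucosyltransferase gene UGT84A1 by 3.97 ± 0.26. Of 8 photosynthesis genes 6 fell, over all genes and adjusted over the list alone, such as the antenna protein gene LHCB4.2 (−2.34 ± 0.29) and ATPC1 (−0.59 ± 0.12). The photosynthesis call (adjusted p = 0.0197) was lost with adjusted p = 0.236 with an estimated correlation, and with 0.196 after median centring and quantile normalisation. Among 19 expansin genes 8 fell (adjusted p = 0.0104, and 0.0636 with an estimated correlation). Among 7 tubulin genes 4 fell, led by TUB1 (−1.94 ± 0.36) (adjusted p = 0.0386, and 0.648 with an estimated correlation). Of 69 chloroplast-encoded genes 7 fell, with rbcL at −1.21 ± 0.33 (adjusted p = 0.00173, and 0.736 with an estimated correlation).

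Camera made no call for the other lists and families in wildtype. Of 3 glucosinolate and tryptophan pathway genes, AT2G04400, an enzyme of tryptophan synthesis, rose by 2.67 ± 0.17, UGT74B1 rose by 0.96 ± 0.28 and BCAT4 of methionine-derived glucosinolates fell by 1.85. Of 4 genes of the auxin, gibberellin and cell expansion list, the auxin-conjugating enzyme gene GH3.3 rose by 2.73 ± 0.21 and EXPA8 fell. Of the 4 reference genes AT4G26410 fell by 0.35. No root marker of 3 passed, with PYK10 at −0.44. For these 4 lists the counts over all genes and adjusted over the list alone were equal. By family, the counts risen and fallen were 5 and 4 of 24 cytochromes P450, 3 and 4 of 14 glutathione transferases, 3 and 3 of 11 thioredoxins and glutaredoxins, 2 and 2 of 10 xyloglucan endotransglucosylases, 1 and 2 of 16 SWEET genes and 2 and 1 of 7 WRKY genes. They were 4 and 0 of 9 calmodulin-like genes, 3 and 0 of 9 U-box genes, 0 and 4 of 8 cellulose synthase and related genes, 0 and 1 of 7 bHLH genes and 0 and 0 of 5 LEA genes. The U-box genes that rose, PUB22 (2.83 ± 0.43), PUB23 (4.12 ± 0.54) and PUB24 (4.33 ± 0.69), encode ubiquitin ligases that restrain immune responses. Among lists with 1 or 2 measured members, the defence factors WRKY6 (4.07 ± 0.37) and WRKY53 (adjusted p = 0.0149) rose, as did HYH of light signalling and UGT84A1 of the phenylpropanoid and sinapate list, whose other member HCT was at −0.23. The values that did not pass were −0.18 for POLH and −0.26 for ATLIG4 of DNA repair, −0.16 for ATHSP22.0 among heat shock proteins, 0.11 for PDF1.2 of jasmonate and wounding, and −0.22 for GI of the circadian clock. SAG29 of leaf senescence was at −0.11 and FMA of the epidermis, trichome and guard cell list at −0.39. Over all contrasts, the camera calls that held with an estimated correlation were those of the UDP-glycosyltransferases, histones and oxidative stress genes for the response of wildtype and of uvr8-1, of the flavonoid and auxin lists for the interaction and for uvr8-1 against wildtype under UV-B, and of the UDP-glycosyltransferases for hy5-1 against wildtype. Of all lists called by camera, fry, which tests whether a list moves on balance 1 way, made no call for the chloroplast-encoded genes in any contrast. The cell cycle, floral, seed storage and vascular lists had 0 measured members.

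The uvr8-1 mutant, tested to see which responses go on without UVR8, responded to UV-B at many of the same genes. AT2G41730 rose by 8.44 ± 0.17, AT1G26380 by 6.99 ± 0.49, AT1G19020 by 6.62 ± 0.42, AT5G51440 by 6.53 ± 0.26 and AT4G39670 by 6.06 ± 0.52. AT2G04050 (6.04 ± 0.27), UGT73B5 (6.01 ± 0.39), AT1G10585 (5.83 ± 0.33), AT3G22060 (5.74 ± 0.61) and AT3G16530 (5.71 ± 0.44) followed. AOP3 fell by 3.87, AT1G13650 by 3.36, EXPA8 by 3.27, AT1G29660 by 3.18 and AT1G54820 by 3.01. AT1G73600, AT5G48490, AT1G26920, AT4G38690 and AT4G28780 had differences of −2.97 ± 0.60, −2.93 ± 0.31, −2.91 ± 0.41, −2.91 ± 0.22 and −2.87 ± 0.19. HYH rose by 2.01 ± 0.45 (adjusted p = 0.00344). Of the 10 largest rises, 7 started from a white light mean under 3.74. The 3' to 5' index was 2.18 ± 0.16 in white light and 1.93 ± 0.02 under UV-B in uvr8-1 (SD, n = 3, exact permutation p = 0.1, the smallest possible). All 3 oxidative stress genes rose, AT2G21640 by 5.48 ± 0.21 (camera adjusted p = 3.88e-05, and 0.02 with an estimated correlation), over all genes and adjusted over the list alone. All 6 histone genes fell (2.9e-05, and 0.0254), and 21 UDP-glycosyltransferase genes rose while 6 fell (2.9e-05, and 0.0086). Of 8 photosynthesis genes 6 fell, 7 adjusted over the list alone (camera adjusted p = 0.00535), a call lost with adjusted p = 0.136 with an estimated correlation. Of 9 calmodulin-like genes 5 rose, among them CML42 at 2.69 ± 0.48 (0.0194), a call lost with adjusted p = 0.161 with an estimated correlation. None of the 7 flavonoid genes rose in uvr8-1, and UGT78D1 fell by 1.39. In all, limma called 2935 probe sets higher and 4320 lower, 1593 and 1358 of them by at least 2-fold. Over all probe sets the responses of the genotypes had a Pearson r of 0.90 and a slope of 0.91 for uvr8-1 on wildtype, although probe sets are not independent replicates.

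**Figure D2:**
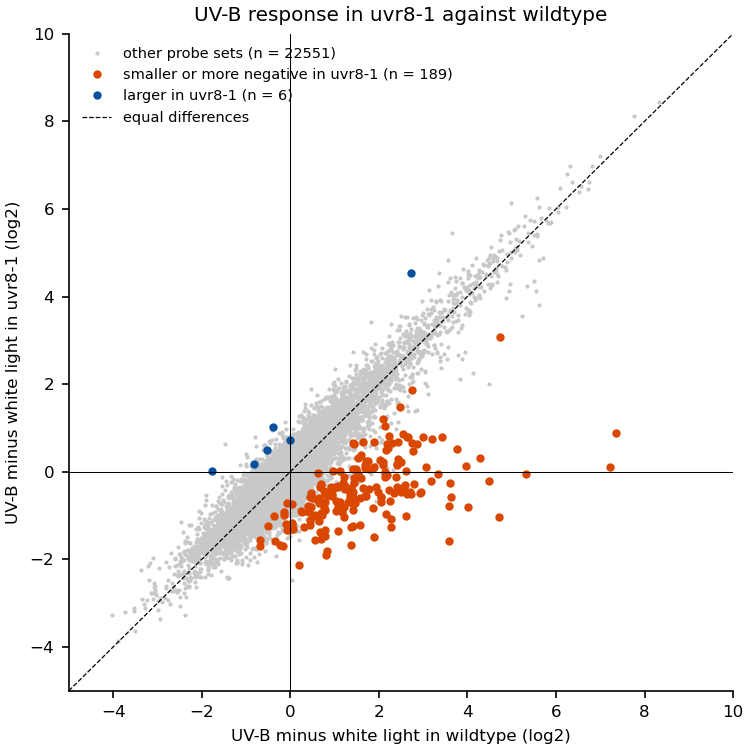
UV-B minus white light in uvr8-1 (vertical axis, log2) against the same difference in wildtype (horizontal axis, log2) for 22746 probe sets; each point is a probe set and the dashed line marks equal responses. Most points follow the line (r = 0.90), and the 189 coloured below it include responses that stay near 0 in uvr8-1.

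The interaction asked which responses differ between the genotypes. Of the 7 flavonoid genes, 4 had a smaller response in uvr8-1, and none of these rose there. UGT78D2 went from 6.14 to 9.10 in wildtype and from 6.28 to 5.82 in uvr8-1, a difference of responses of −3.42 ± 0.32 (adjusted p = 0.000108). DFR was at −3.34 ± 0.59, CHIL at −3.16 ± 0.47 and AT1G06000 at −3.07 ± 0.57. UGT84A1, of the phenylpropanoid and sinapate list, was at −3.83 ± 0.37. The largest difference of a named gene was that of AT5G62210 (−4.37 ± 0.42, adjusted p = 0.000132). AT3G52740, whose product inhibits cryptochrome photoreceptors (−3.42 ± 0.44), AT3G57020 (−3.39 ± 0.42), AT5G42760 (−3.23 ± 0.57) and AT3G56290 (−3.11 ± 0.38) also had smaller responses. Beyond these, 7 probe sets that the annotation used here does not pair with a single gene had still lower values, down to −7.11 ± 0.33 for 258321_at and −6.47 ± 0.33 for 245306_at. HYH, at −2.47 ± 0.63, did not pass (adjusted p = 0.135). Responses larger in uvr8-1 were found for GH3.3 (1.81 ± 0.30, adjusted p = 0.00853), UGT72E1 of phenylpropanoid glucosylation (1.41 ± 0.27, 0.0238) and AT3G01720 (0.73 ± 0.14, 0.0234). GH3.3 rose by 2.73 in wildtype and by 4.55 in uvr8-1. Adjusted over the list alone, the difference of responses was called negative for 6 of the flavonoid genes, against 4 over all genes (camera adjusted p = 5.26e-13, and 0.0316 with an estimated correlation). The auxin, gibberellin and cell expansion list was placed up (0.000216, and 0.0316 with an estimated correlation), with GH3.3 the 1 call over all genes and 2 adjusted over the list alone. No chloroplast-encoded gene passed, and that family's camera call (adjusted p = 0.018) was lost with adjusted p = 0.909 with an estimated correlation. In all, limma called 6 probe sets higher and 189 lower, and 1609 had an unadjusted p under 0.05. Higher and lower here give the sign of the difference of responses, not the size of a response. A higher call can also be a fall in wildtype that is absent in uvr8-1, as for 263443_at. Its mean went from 7.65 to 5.89 in wildtype and from 7.42 to 7.44 in uvr8-1.

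Without wildtype UV-B replicate 3, the lower calls of the interaction numbered 294 and the higher ones 40. The higher calls numbered 14 without uvr8-1 UV-B replicate 1 and 3 without wildtype UV-B replicate 1 or 2. They numbered 1 without wildtype white light replicate 2, 2 without wildtype white light replicate 3 and 2 without uvr8-1 white light replicate 1. With replicate number as a block they numbered 10. The calls of UGT72E1, AT3G01720 and AT1G06000 ended in 7, 8 and 6 of the 12 fits without 1 array, with adjusted p up to 0.0751 without wildtype white light replicate 3, 0.0759 without wildtype UV-B replicate 2 and 0.0647 without uvr8-1 white light replicate 2. With a block over the 12 wildtype and uvr8-1 arrays, AT3G01720 and AT5G42760 were no longer called (adjusted p = 0.0619 and 0.0628). AT3G01720 was not called with an intensity trend (adjusted p = 0.122), nor UGT72E1 in a fit of only the 4 compared groups (0.0663). With the 3' to 5' index as a covariate, the interaction gave 1 higher and 128 lower calls. The calls of UGT72E1 (0.116), AT3G01720 (0.11), AT5G42760 (0.0814) and AT1G06000 (0.0583) then ended.

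**Figure D3:**
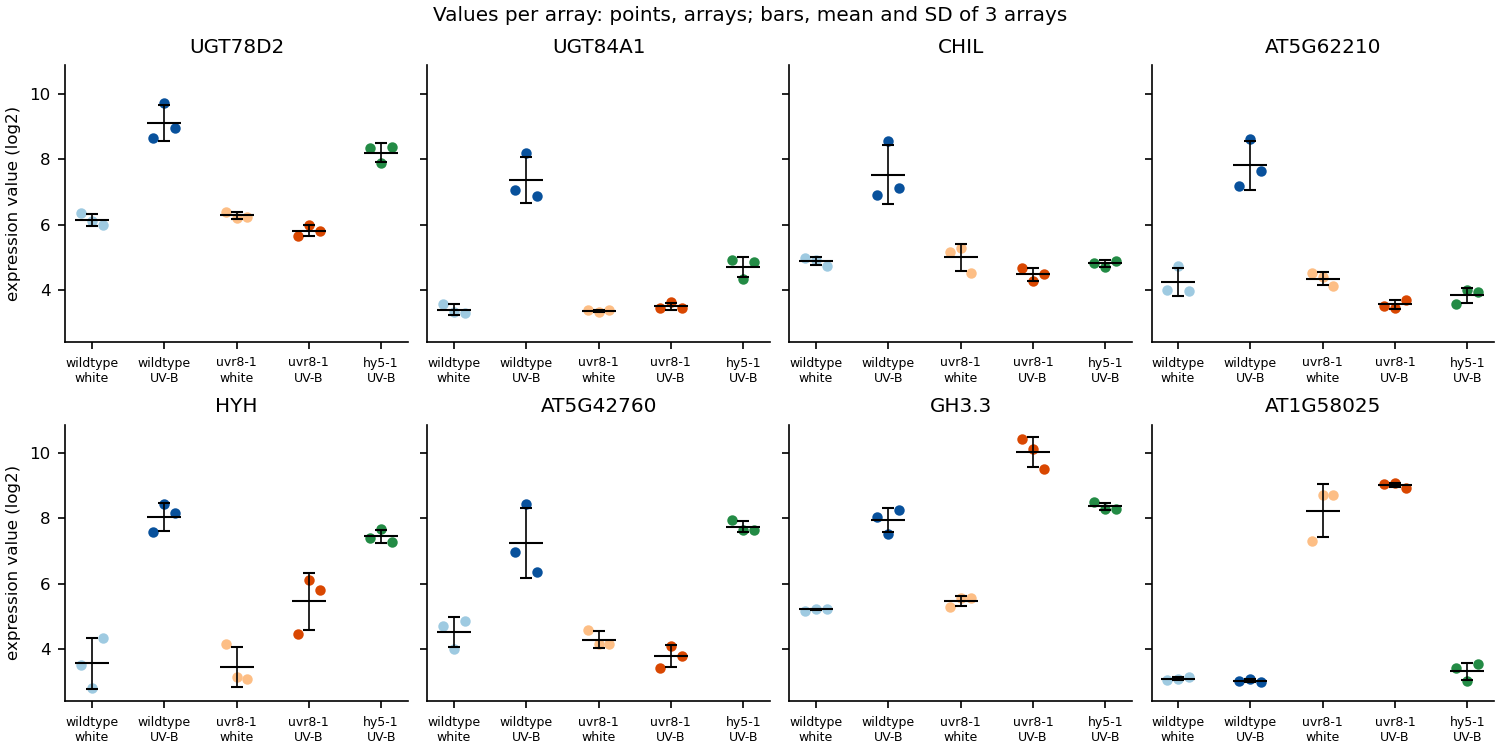
Expression values in log2 units (vertical axis) of 8 genes on each of the 15 arrays, by group (horizontal axis); points are arrays and bars give mean and SD of 3 arrays. UGT78D2, UGT84A1, CHIL and AT5G62210 rise under UV-B in wildtype and not in uvr8-1, whereas AT1G58025 is higher in uvr8-1 in both lights, with 8.23 and 9.01 against 3.10 and 3.04.

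Levels under UV-B were compared directly between uvr8-1 and wildtype. AT5G62210 (−4.25 ± 0.30), UGT84A1 (−3.86 ± 0.26), AT3G57020 (−3.75 ± 0.30), AT3G52740 (−3.52 ± 0.31) and AT5G42760 (−3.47 ± 0.40) were lower in uvr8-1. So were AT3G56290 (−3.35 ± 0.27), UGT78D2 (−3.29 ± 0.23), DFR (−3.12 ± 0.42), CHIL (−3.04 ± 0.33) and AT5G35970 (−3.04 ± 0.42), with adjusted p between 1.83e-06 and 0.000923. HYH was lower by −2.59 ± 0.45 (adjusted p = 0.00539). Higher in uvr8-1 were AT1G58025 (5.97 ± 0.28), GH3.3 (2.07 ± 0.21), the small heat shock protein gene AT2G29500 (1.46 ± 0.27), AT1G12080 (1.44 ± 0.32) and MYC3, a transcription factor of jasmonate signalling (1.26 ± 0.19). The means of MYC3 were also apart in white light, at 6.54 in uvr8-1 and 5.43 in wildtype, although that difference was not called. UGT72E1 (1.25 ± 0.19), AT5G59080 (1.17 ± 0.25), the auxin-conjugating enzyme gene WES1 (1.14 ± 0.24), GSTU22 (1.09 ± 0.24) and AT5G10830 (1.04 ± 0.19) followed. Of the 7 flavonoid genes 6 were lower, over all genes and adjusted over the list alone (camera adjusted p = 4.74e-14, and 0.0245 with an estimated correlation). In the auxin list 2 of 4 were higher, by both counts (1.69e-05, and 0.0146 with an estimated correlation). Beyond the named genes, 9 probe sets without a paired gene were lower still, with 258321_at at −7.29 ± 0.23 and 245306_at at −6.53 ± 0.24. In all, limma called 96 probe sets higher and 453 lower. The 96 became 36, 44 and 258 without wildtype UV-B replicates 1, 2 and 3, and 59 and 63 without uvr8-1 UV-B replicates 2 and 3. With the replicate block they became 159. The calls of AT1G12080, AT5G59080, WES1 and GSTU22 ended in 5, 4, 4 and 5 of the 6 fits without 1 array, with adjusted p up to 0.112 without wildtype UV-B replicate 1 for AT1G12080, 0.112 without wildtype UV-B replicate 2 for AT5G59080 and GSTU22, and 0.111 without wildtype UV-B replicate 1 for WES1. A fit of only these groups ended the calls of HYH (0.0726), AT2G29500 (0.195), AT5G59080 (0.0545), WES1 (0.109), GSTU22 (0.286) and AT5G10830 (0.16), and array weights those of AT2G29500 (0.0708) and GSTU22 (0.15).

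In white light, where UVR8 is not activated by UV-B, 4 probe sets differed between uvr8-1 and wildtype, and 371 had an unadjusted p under 0.05. AT1G58025 was higher in uvr8-1 by 5.13 ± 0.28 (adjusted p = 2.55e-06). The other 3, named after their values were seen, were 254452_at (2.01 ± 0.20), 248863_at (0.93 ± 0.10) and 263001_at (−1.36 ± 0.14), each at an adjusted p of 0.00181 and none paired with a gene here. Under UV-B the uvr8-1 minus wildtype differences were 1.71 for 254452_at and −1.32 for 263001_at, and 248863_at had means of 8.52 in uvr8-1 and 7.36 in wildtype. In hy5-1 under UV-B, 248863_at had a mean of 8.39. The mean of 254452_at was 4.25 there, against 4.52 in uvr8-1 and 2.81 in wildtype, so both lay nearer to uvr8-1. That of 263001_at was 7.06 in hy5-1, 5.36 in uvr8-1 and 6.67 in wildtype. HYH did not differ (−0.11 ± 0.45, adjusted p = 1). No member of any list passed. The chloroplast-encoded family was placed down by camera (adjusted p = 3.64e-05), a call lost with adjusted p = 0.78 with an estimated correlation. The 3' to 5' index was 2.18 ± 0.16 in uvr8-1 and 1.83 ± 0.04 in wildtype in these arrays (SD, n = 3). In a limma fit of only these groups no probe set was called, with AT1G58025 at an adjusted p of 0.0578.

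The 1602 probe sets induced at least 2-fold in wildtype were classed by their behaviour in the mutants. In uvr8-1, 1400 of them (87.4%) were also called higher under UV-B, and 1272 by at least 2-fold. The response was smaller in uvr8-1 for 128 (8.0%) by the interaction, 173 adjusted over the list alone, and larger for 1, 5 adjusted over the list alone. Of the 128, 74 had no call in either direction in uvr8-1, 24 still rose and the rest were called lower under UV-B than in white light there. Under UV-B, 186 were lower in uvr8-1 than in wildtype (232 adjusted over the list alone) and 5 were higher. In hy5-1, 223 were lower (299 adjusted over the list alone) and 28 higher. The 223 became 103 and 134 without hy5-1 replicates 2 and 1, and 129 without wildtype UV-B replicate 2. The response was smaller in uvr8-1 and the level lower in hy5-1 for 83, and for 45 the response was smaller in uvr8-1 without a call of lower in hy5-1. A further 140 were lower in hy5-1 without a smaller response in uvr8-1. The hy5-1 arrays had the higher 3' to 5' index, and with it as a covariate 1 of the 83 and 0 of the 140 were still called. There the standard error of hy5-1 against wildtype was 2.36 times as large at the median over all probe sets. In 20 simulated data sets with unchanged mutants, which share the wildtype arrays in the same way, 1657 probe sets were induced on average, 1582 of them also higher in uvr8-1 and 1442 by at least 2-fold. With the residuals of equally numbered wildtype and uvr8-1 arrays correlated as observed, these were 1657, 1618 and 1510. The classes with a smaller or larger response or a lower or higher level in a mutant had a simulated mean of 0 over all genes, and of at most 0.05 with the correlated residuals. Both simulations kept probe sets independent of each other and mutants equal to wildtype, so almost no such calls could arise.

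**Figure D4:**
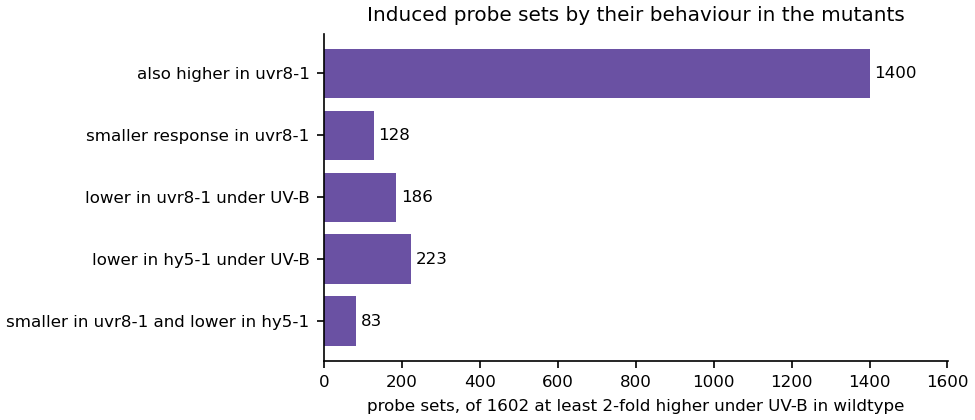
Number of probe sets (horizontal axis) among the 1602 induced in wildtype that fall in each class (vertical axis); classes overlap. The class also higher in uvr8-1 holds 1400, that with a smaller response in uvr8-1 holds 128, and 83 are both smaller in uvr8-1 and lower in hy5-1.

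The hy5-1 arrays allowed a comparison of levels under UV-B only. Compared with wildtype, AT5G62210 (−3.97 ± 0.30), CHIL (−2.71 ± 0.33), UGT84A1 (−2.66 ± 0.26), the methyltransferase gene AT1G29470 (−2.54 ± 0.14) and the peptide gene RALFL32 (−2.33 ± 0.27) were lower. AT2G23910 (−2.32 ± 0.43), DFR (−2.18 ± 0.42), AT5G04810 (−2.17 ± 0.23), the chloroplast ribosomal protein gene rpl36 (−2.11 ± 0.45) and AT3G45160 (−2.06 ± 0.36) were lower too. Higher in hy5-1 were the lipid transfer protein genes AT4G12490 (3.21 ± 0.68) and AT4G22470 (2.08 ± 0.34), AT1G55960 (2.35 ± 0.39), the lectin gene AT5G03350 (2.29 ± 0.36) and the methionine sulfoxide reductase gene MSRB9 (2.05 ± 0.39). The thionin gene THI2.2 (2.04 ± 0.49), the jasmonate-regulated gene JRG21 (1.64 ± 0.37), AT2G16630 (1.63 ± 0.31), the cell wall protein gene HRGP1 (1.62 ± 0.31) and AT1G10340 (1.60 ± 0.33) were higher as well. HYH stood at 7.45 ± 0.21 in hy5-1 and 8.05 ± 0.43 in wildtype (SD, n = 3), and the difference of −0.61 ± 0.45 did not pass (adjusted p = 0.431). Of the 7 flavonoid genes 6 were lower, over all genes and adjusted over the list alone, with UGT78D2 at −0.91 ± 0.23, and the camera call (adjusted p = 2.6e-06) was lost with adjusted p = 0.123 with an estimated correlation. Of the 52 UDP-glycosyltransferase genes 7 were lower (0.000704, and 0.0326 with an estimated correlation). The hy5-1 arrays also had the higher 3' to 5' index, 2.78 ± 0.32 against 1.88 ± 0.10 in wildtype (SD, n = 3), which applies to the flavonoid and glycosyltransferase genes as to those that follow.

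Further groups were lower in hy5-1 than in wildtype on these arrays of higher 3' to 5' index. Of 7 tubulin genes 5 were lower, led by TUB5 (−1.83 ± 0.27) and TUB7 (−1.61 ± 0.31), with a camera adjusted p of 5.15e-06 that became adjusted p = 0.199 with an estimated correlation. Of 6 histone genes 4 were lower, with HTB11 at −0.86 ± 0.11 (0.00609), a call lost with adjusted p = 0.123 with an estimated correlation. Of 3 oxidative stress genes GSTU25 (−1.36 ± 0.33) and AT2G21640 (−1.27 ± 0.21) were lower, by both counts (0.0166), a call lost with adjusted p = 0.123 with an estimated correlation. Among chloroplast-encoded genes rpl36 and rpl22 (−1.43 ± 0.34) were lower (camera adjusted p = 0.0162), a call lost with adjusted p = 0.761 with an estimated correlation and with 0.176 after renormalisation. The glucosinolate and tryptophan list had 0 calls over all genes and 1 lower adjusted over the list alone, and its camera call (0.0274) was lost with adjusted p = 0.199 with an estimated correlation and with 0.0919 after renormalisation. The expansin family was placed up by camera (0.0177), with 0 of 19 members called and adjusted p = 0.123 with an estimated correlation. In all, limma called 631 probe sets higher and 1095 lower. These became 187 and 363 without hy5-1 replicate 2, 225 and 478 without hy5-1 replicate 1, and 223 and 456 without wildtype UV-B replicate 2, and the higher ones became 376 without wildtype UV-B replicate 3. With the 3' to 5' index as a covariate, limma called 0 higher and 2 lower, on a standard error 2.36 times as large at the median. With the hy5-1 array of lowest index alone, the differences over all probe sets had an r of 0.889 with those from all 3 hy5-1 arrays, which include that array. The calls of AT4G12490, THI2.2, JRG21, AT1G10340, DFR and rpl36 ended in 2, 4, 3, 2, 1 and 3 of the 6 fits without 1 array. The highest adjusted p were 0.0653, 0.102 and 0.0783 without wildtype UV-B replicate 2 for AT4G12490, THI2.2 and JRG21, and 0.064, 0.051 and 0.0677 without hy5-1 replicate 2 for AT1G10340, DFR and rpl36. A fit of only these groups ended the calls of THI2.2 (0.055) and JRG21 (0.0644).

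Between the mutants under UV-B, several genes with a smaller response in uvr8-1 were higher in hy5-1. AT5G42760 was higher in hy5-1 by 3.97 ± 0.40, AT3G56290 by 3.11 ± 0.27, AT3G57020 by 2.98 ± 0.30, AT5G35970 by 2.52 ± 0.42 and UGT78D2 by 2.38 ± 0.23. HYH was higher by 1.98 ± 0.45 (adjusted p = 0.0123, and 0.0532 without hy5-1 replicate 2). Also higher were AT4G12490 (3.74 ± 0.68), the receptor kinase gene AT1G16260 (3.19 ± 0.30), AT1G55960 (2.78 ± 0.39), THI2.2 (2.73 ± 0.49), AT3G44450, a relative of AT3G52740 (2.71 ± 0.46), and AT5G03350 (2.42 ± 0.36). The unpaired probe sets 245306_at and 258321_at exceeded them, at 5.15 ± 0.24 and 4.97 ± 0.23. Lower in hy5-1 were AT1G58025 (−5.68 ± 0.28), AT3G29075 (−2.89 ± 0.77), CCT1 of phosphatidylcholine synthesis (−2.80 ± 0.41), AT1G29470 (−2.79 ± 0.14) and GSTU25 (−2.68 ± 0.33). AT1G62480 (−2.59 ± 0.31), AT3G60300 (−2.56 ± 0.38), AT2G31410 (−2.55 ± 0.61), rpl36 (−2.54 ± 0.45) and AT5G53880 (−2.41 ± 0.67) were lower too. The flavonoid list had 1 call, UGT78D2, over all genes and adjusted over the list alone, and no camera call (adjusted p = 0.155). Several groups were lower in hy5-1, whose 3' to 5' index of 2.78 ± 0.32 compared with 1.93 ± 0.02 in uvr8-1 under UV-B (SD, n = 3). Of 7 tubulin genes 6 were lower (2.74e-06, and adjusted p = 0.207 with an estimated correlation), of 6 histone genes 3 (0.00179, and adjusted p = 0.206 with an estimated correlation) and of 3 oxidative stress genes 2 by both counts (0.0132, and adjusted p = 0.206 with an estimated correlation). In the glucosinolate and tryptophan list 2 of 3 were lower, 3 adjusted over the list alone (0.0159, and adjusted p = 0.207 with an estimated correlation). In the auxin list 2 of 4 were lower by both counts (0.0481, adjusted p = 0.207 with an estimated correlation and 0.139 after renormalisation). Of 69 chloroplast-encoded genes 4 were lower (0.0132, adjusted p = 0.849 with an estimated correlation and 0.0948 after renormalisation). Of 16 SWEET genes SWEET2 (2.09 ± 0.28) and SWEET16 (0.53 ± 0.15) were higher (0.0477, adjusted p = 0.414 with an estimated correlation and 0.0836 after renormalisation).

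In all, limma called 1222 probe sets higher and 1926 lower in hy5-1 than in uvr8-1. These became 601 and 992 without hy5-1 replicate 1, 603 and 890 without hy5-1 replicate 2, and 632 and 1092 without uvr8-1 UV-B replicate 2, and the higher ones became 723 without uvr8-1 UV-B replicate 3. With the 3' to 5' index as a covariate there were 6 and 2, on a standard error 2.25 times as large at the median. With the hy5-1 array of lowest index alone, the differences had an r of 0.92 with those from all 3 hy5-1 arrays, which include that array. The calls of AT3G29075, AT2G31410 and AT5G53880 ended in 4, 3 and 5 of the 6 fits without 1 array, with adjusted p up to 0.107, 0.0631 and 0.128 without uvr8-1 UV-B replicate 2.

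The mutants overlapped in the probe sets that differed from wildtype under UV-B. Among those lower in both were AT5G62210, UGT84A1, CHIL and DFR. In all, 190 probe sets were lower in both, where independent calls would give 21.8, 14 were higher in both against 2.66, and 8 went in opposite directions. The covariance of the differences over all probe sets was 0.0328, against 0.0199 (0.0184 to 0.0222) in 20 simulated data sets with unchanged mutants and the same shared wildtype arrays, which gave 0 probe sets lower in both. Those simulations treat all arrays as independent, whereas equally numbered wildtype and uvr8-1 arrays correlated. With the residuals correlated as observed, the simulated covariance was 0.00888 (0.00796 to 0.01) and again 0 probe sets were lower in both. Probe sets were independent of each other in both simulations, so almost no mutant calls could arise. The correlation of the differences was 0.246, against a simulated 0.506 (0.484 to 0.529) with independent and 0.339 (0.314 to 0.364) with correlated residuals. The 3 wildtype arrays cannot be divided so that each mutant has at least 2 of its own, so the share of the excess that comes from shared controls was not separated. The 190 became 102 and 113 without wildtype UV-B replicate 2 and hy5-1 replicate 2. The 14 became 34, 6 and 7 without wildtype UV-B replicates 3, 2 and 1, 9 without uvr8-1 UV-B replicate 3, and 7 and 9 without hy5-1 replicates 1 and 2. The higher 3' to 5' index of the hy5-1 arrays applies here as well. With it as a covariate, limma called 0 probe sets higher and 2 lower in hy5-1 than in wildtype, so almost no overlap was left. The standard error was then 2.36 times as large at the median.

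**Figure D5:**
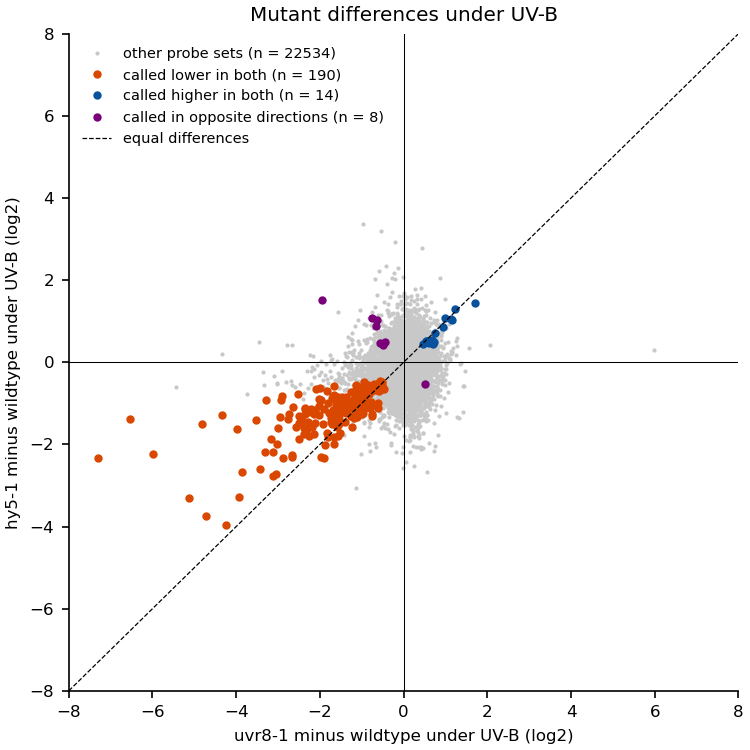
hy5-1 minus wildtype (vertical axis, log2) against uvr8-1 minus wildtype (horizontal axis, log2) under UV-B for 22746 probe sets; each point is a probe set and the dashed line marks equal differences. Of the coloured points 190 are lower in both mutants, 14 are higher in both and 8 differ in direction.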

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

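Chosen after the result was seen were the shift predicted from 12 arrays, the test of value range for the replicate 1 arrays, and every fit with the 3' to 5' index or without the replicate 1 arrays.

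The following differed between the genotypes by the interaction test, which compares the UV-B response of uvr8-1 with that of wildtype. Smaller responses in uvr8-1 were those of UGT84A1 (−3.83), UGT78D2 (−3.42), DFR (−3.34), CHIL (−3.16) and AT1G06000 (−3.07). So were those of AT5G62210 (−4.37), AT3G52740 (−3.42), AT3G57020 (−3.39), AT5G42760 (−3.23) and AT3G56290 (−3.11). Larger responses were those of GH3.3 (1.81), UGT72E1 (1.41) and AT3G01720 (0.73). By list, the median difference of responses was −3.07 for the flavonoid pathway, 0.84 for auxin, gibberellin and cell expansion and 0.38 for the chloroplast-encoded genes. No chloroplast-encoded gene passed alone, and that family's camera call was lost with an estimated correlation (adjusted p = 0.909) and was not made by fry (0.878). The control probe sets, which the comparisons do not use, gave a GAPDH 3' minus 5' value that was higher by 1.68 in hy5-1 than in wildtype under UV-B. The actin value was higher by 0.38 (exact permutation p = 0.3).

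Other splits of the arrays were fitted in the same way. For the interaction, 7 of 100 drawn splits of genotype within light, of 200 possible, gave at least the 195 calls of the real split, which is 1 of the 7, and the highest of the others gave 264, so chance is not excluded by this count. All 7 are among the 8 drawn splits that keep the real genotypes under UV-B, of which all but the real one mix only the white light arrays, where 4 probe sets differed. Those 8 gave at least 186 calls, and the highest count without the real genotypes under UV-B was 167. For the other contrasts the 10 splits are too few for a share under 0.05, and 1 split, the real one, gave as many calls in each. The real count and the highest other were 6941 and 1 for UV-B in wildtype, 7255 and 0 for UV-B in uvr8-1, 4 and 3 for uvr8-1 against wildtype in white light, 1726 and 1 for hy5-1 against wildtype, and 3148 and 1 for hy5-1 against uvr8-1. For uvr8-1 against wildtype under UV-B they were 549 and 346, and the other splits that hold all 3 replicate numbers in each part gave 0. The split with 346 sets wildtype replicates 1 and 2 and uvr8-1 replicate 1 against wildtype replicate 3 and uvr8-1 replicates 2 and 3, which points to a structure of these arrays apart from genotype.

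For the 83 induced probe sets lower in hy5-1 with a smaller response in uvr8-1, 3' bias of the hy5-1 arrays was weighed as a cause. The shift predicted from the slope on the 3' to 5' index within the groups was 0.0302, against −1.35 observed. That result met the limit set beforehand for arguing against 3' bias, although the fit that gave the slope was chosen after the data were seen. From the 12 arrays of the other groups the predicted shift was 0.65. Neither value excludes 3' bias. The index varied most within hy5-1 (SD 0.32), which weighs on the first slope. The slope from the 12 arrays also followed the UV-B response of wildtype (r = 0.343). With the index as a covariate −1.46 remained, of the same sign in 81, but the standard error was 2.36 times as large at the median over all probe sets and 1 of the 83 was still called. Shared wildtype arrays were not excluded: chosen without wildtype UV-B replicate 1, 2 or 3 in turn, the class lay below the other induced probe sets by −1.07, −1.24 and −0.196 when hy5-1 was set against the array left out, and the smallest of these is within the limit set beforehand for this explanation. That value rests on replicate 3 alone, against which the other induced probe sets lay at −0.41 and 116 of the 144 in the class below 0. Simulations with unchanged mutants gave 0 probe sets in this class. They kept probe sets independent of each other, so almost no mutant calls could arise, and they do not decide the question. A loss of HY5 function is the biological explanation the design offers and stays open, as no hy5-1 array in white light was made.

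AT1G58025 was higher in uvr8-1 than in wildtype in white light (5.13) and under UV-B (5.97), with a lowest value of 7.29 on a uvr8-1 array and a highest of 3.54 on any other. A chromosomal segment that differs between the lines and changes its genes was weighed with the 20 nearest genes that have a single-gene probe set. In white light 0 of the 20 had an unadjusted limma p under 0.05, as did 1.63% of all probe sets, and their largest difference was 0.32. That met the limit set beforehand for arguing against a segment. Only 9 of the 20 lay above the dimmest 40% of probe sets, and probe sets without a single paired gene were left out. The result therefore argues against a segment only for the genes that could show a change. Under UV-B 2 of the 20 had such a p, AT1G57770 (−2.26, with 0.01 in white light) and AT1G58110 (0.35), while 12% of all probe sets did. A variant at this locus alone may remain, and it was not tested. An effect of UVR8 that needs no UV-B is the biological explanation the design offers, and with 1 mutant line it was not separated from such a variant.

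The UV-B response of replicate 1 was smaller in both genotypes, with slopes 0.796 and 0.737 times those of the other replicates in wildtype and uvr8-1. A narrower range of values on the replicate 1 arrays was not decided: their SD over probe sets was 0.967 of that of the others, but RMA brings arrays to a common distribution, and no array had less than 0.932 of the highest SD. The probe sets with smaller responses in uvr8-1 rose in wildtype by a median of 1.95, 2.39 and 1.77 in replicates 1, 2 and 3. A weaker or shorter exposure of that replicate may also account for the pattern, but the labels give the same exposure and this was not tested.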

How the results depend on the processing

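The block over 12 arrays, the fits without replicate 1, the fits and shifts with the 3' to 5' index and those with 1 hy5-1 array were chosen after seeing the data. Probe sets near background limit what can be seen: the dimmest 40% had means under 3.74, where a fall has little room and the size of a rise depends on background, and 13647 probe sets remained without them. Of 121 values of named genes, all kept their direction and side of the threshold with the replicate block and with median centring and quantile normalisation. So did 120 with an intensity trend, 119 with array weights, 111 in fits of only the compared groups and 77 of 79 with the block over 12 arrays, and 79 of 121 with the index as a covariate. Apart from the changes given here and beside the results, the replicate block ended no call of a named gene and 1 of a list, auxin, gibberellin and cell expansion for hy5-1 against uvr8-1 (adjusted p = 0.0786). Blocking on replicate kept 180 of the 195 interaction calls over 15 arrays and 150 over 12. Among lists, 23 camera calls were lost with an estimated correlation, 6 after renormalisation and 5 by fry, which added 26. HYH in white light, at −0.11, ranged from −0.49 to 0.28 when an array was left out and so reversed in sign, without a call. Removing probe sets that may bind several transcripts moved no count by more than 1.5 times.

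Counts that moved by more than 1.5 times are given as higher then lower, and the cause was not tested unless stated. With the replicate block, 10 probe sets were higher by the interaction, 159 were higher in uvr8-1 and 1226 in hy5-1 than in wildtype under UV-B, and 29 were higher in both mutants. Over 12 arrays, the first of these numbers was 10 and the second 178. In fits of only the compared groups, which have fewer residual degrees of freedom, 3 probe sets were higher by the interaction. In these fits 17 and 196 probe sets differed between uvr8-1 and wildtype under UV-B and 0 and 0 in white light (limma). Between hy5-1 and wildtype 223 and 564 differed, and 781 were higher in hy5-1 than in uvr8-1. With an intensity trend, 61 were higher in uvr8-1 than in wildtype and 8 in both mutants. With array weights, the interaction gave 28 and 306, 202 were higher in uvr8-1 than in wildtype under UV-B, 2248 in hy5-1 than in uvr8-1 and 24 in both mutants. After renormalisation 22 were higher in both mutants, and without the dimmest 40% 406 were higher in hy5-1 than in wildtype. A 2-fold minimum, lower by construction, gave 1602 and 1227 in wildtype, 1593 and 1358 in uvr8-1, 15 and 280 for uvr8-1 against wildtype under UV-B, 76 and 329 for hy5-1 against wildtype and 270 and 482 against uvr8-1. It left 122 induced probe sets lower in hy5-1, 4 higher in both mutants and 100 lower in both. The rank product gave 640 and 508 in wildtype, 601 and 471 in uvr8-1, 16 and 283 for uvr8-1 against wildtype under UV-B, 6 higher in white light, 137 and 291 for hy5-1 against wildtype and 287 and 297 against uvr8-1.

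Without the replicate 1 arrays, and so with fewer arrays, the interaction gave 3 and 81, uvr8-1 against wildtype 39 and 297 under UV-B and 0 lower in white light, 68 induced probe sets had a smaller response in uvr8-1 and 6 were higher in both mutants. With the index as a covariate, 1 probe set was higher by the interaction and 1 was higher in uvr8-1 in white light. hy5-1 then differed from wildtype in 0 and 2 probe sets and from uvr8-1 in 6 and 2, 1 induced probe set was lower in hy5-1, and 0 and 1 were higher and lower in both mutants. There the standard error of hy5-1 against wildtype was 2.36 times as large at the median. The shift predicted from the index was −0.40 of a median −0.75 for the 872 probe sets lower in hy5-1 that were not induced (−0.30 from the slope in the 12 other arrays), so 3' bias of the hy5-1 arrays may account for part of these differences. It was −0.23 of −0.94 for the 140 induced probe sets lower in hy5-1 without a smaller response in uvr8-1, and 0.20 of 0.60 for the 631 higher ones, but 0.21 and 0.11 from the 12 arrays, the first opposite in sign to the difference. Over all probe sets the r of 0.184 between index slope and hy5-1 minus wildtype difference decided nothing, since it was 0.343 for UV-B in wildtype, where the index differed by 0.05. With the hy5-1 array of lowest index alone, whose spread is assumed to be that of the other groups, the counts were 6 and 23 against wildtype, 66 and 35 against uvr8-1, 17 induced probe sets lower in hy5-1, and 1 and 19 higher and lower in both mutants.

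Leaving out each array in turn gave 1 to 40 higher and 127 to 294 lower calls for the interaction. It gave 36 to 258 probe sets higher in uvr8-1 than in wildtype under UV-B. It gave 187 to 772 and 363 to 1241 for hy5-1 against wildtype, 601 to 1277 and 890 to 2045 against uvr8-1, 103 to 256 induced probe sets lower in hy5-1, and 6 to 34 higher and 102 to 251 lower in both mutants. The lowest and highest came from the arrays named beside these results or moved the count by less than 1.5 times. No count of UV-B responses within a genotype moved by more than 1.5 times, at 2351 to 2924 higher and 3254 to 4342 lower in wildtype and 2393 to 2973 and 3501 to 4385 in uvr8-1. Neither did the induced probe sets, at 1467 to 1750, nor those with a smaller response in uvr8-1, at 96 to 144.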

Other observations

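Members of several gene families changed under UV-B in wildtype. Among glutathione transferases, GSTU25 rose by 3.55 ± 0.33 and GSTU28 by 2.11 ± 0.22, while GSTU20 fell by 1.36. Among xyloglucan endotransglucosylases, enzymes of the cell wall, XTH18 rose by 2.04 ± 0.60 and XTH16 fell by 2.61. The calmodulin-like genes CML37 (2.90 ± 0.71), CML38 (2.72 ± 0.58) and CML42 (2.74 ± 0.48) rose, as did GRX480, a glutaredoxin gene of salicylate signalling (3.11 ± 0.57), and, of 24 cytochrome P450 genes of which 5 rose and 4 fell, CYP71B6 (2.24 ± 0.25) and CYP71B23 (2.84 ± 0.37). The sugar transporter gene SWEET2 rose by 2.63 ± 0.28 and SWEET17 fell by 1.37.

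Genes with a smaller UV-B response in uvr8-1 stood at different levels in hy5-1. Means under UV-B in wildtype, uvr8-1 and hy5-1 were 7.81, 3.56 and 3.84 for AT5G62210 and 7.52, 4.48 and 4.81 for CHIL. They were 9.10, 5.82 and 8.20 for UGT78D2 and 7.25, 3.78 and 7.75 for AT5G42760. For the unpaired probe sets 258321_at and 245306_at they were 10.93, 3.63 and 8.60, and 11.55, 5.02 and 10.18.

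A control probe set of 25S ribosomal RNA was highest on the replicate 3 array in wildtype in white light (4.64), wildtype under UV-B (5.13), uvr8-1 in white light (4.91) and uvr8-1 under UV-B (6.10). On the hy5-1 arrays it was 2.88, 2.84 and 2.98.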
